A study of Shewanella oneidensis and Geobacter metallireducens
Geobacter sulfurreducens
Shewanella oneidensis and Geobacter sulfurreducens with 18 samples.

How the data were processed

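RNA was sequenced from anode biofilms and planktonic cells of bio-electrochemical systems that held Shewanella oneidensis, Geobacter sulfurreducens, Geobacter metallireducens or all 3 species together. Per the labels, total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced as read pairs, at 51 nt for the pure S. oneidensis and G. sulfurreducens cultures and at 100 nt for the pure G. metallireducens and the mixed cultures. The 18 libraries form 6 groups of 3, taken from the sample titles. Whether a replicate number marks a shared reactor is not given in the sources used here.

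The values are read counts per locus tag as deposited by the authors, 1 file per library for pure cultures and 1 file per library and species for the mixed culture, 30 files in all. The deposited counts are whole numbers and unnormalized. The processing notes of the submitters name CASAVA 1.8.1, Bowtie2 and HTSeq without saying what each was used for, and the parameters and genome builds are not given in the sources used here. Each file closes with the tallies of reads that were given to no gene. The tally for low alignment quality made up 74.6 to 95.3% of the total of a library (median 90.0%), and reads in named genes 0.719 to 4.21%. In each of the 6 mixed libraries the files of the 3 species share the same tallies of unaligned and low-quality reads. The ratio of reads in no gene of any of the species to reads in genes ran from 0.462 to 3.67 (median 2.05).

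Of 4214 S. oneidensis locus tags in the files, 4162 were found in the reference table of RefSeq genes and 1219 had a symbol. Genes without a symbol are given by locus tag. The matched tags held 0 genes of ribosomal, transfer or other structural RNA, so leaving such genes out changes nothing for S. oneidensis. This was not tried for the 2 Geobacter species (3430 and 3549 tags), whose gene types and names were not used here. What a gene is known to do is given from general knowledge of these species.

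Gene counts per library ran from 59116 to 1575571 for S. oneidensis, from 6093 to 432055 for G. sulfurreducens and from 342 to 76590 for G. metallireducens. Counts were simulated with 1 dispersion for all genes of a species, the median of the values fitted per gene (0.0745 for S. oneidensis, 0.0314 for G. sulfurreducens and 0.0609 for G. metallireducens). These lie below the common dispersions given further on, clearly so for the first 2 species, so the shares recovered are likely too high for genes that vary more. In this simulation 2-fold changes were recovered in 41% of changed genes for pure S. oneidensis anode against planktonic cells, 20% for the mixed culture and 24% for mixed against pure anode biofilms. The shares were 71% and 24% for the G. sulfurreducens comparisons (mixed against pure, and mixed anode against planktonic) and 45% and 20% for those of G. metallireducens. At 4-fold the shares were 97, 88, 87, 100, 79, 92 and 41% in the same order. For mixed anode against planktonic cells the log2 estimates of G. metallireducens exceeded the simulated changes by a median of 1.18 at 2-fold and 1.14 at 4-fold, and all changes recovered for it there were rises although as many falls as rises were simulated. The estimates of G. sulfurreducens exceeded theirs by 0.16 and 0.14. In the other comparisons the median error lay between -0.11 and 0.01.

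Replicates within each group were compared by a chi-square test on genes with at least 20 summed counts. The pure G. sulfurreducens libraries titled 1 and 3 differed no more than repeated sampling of one library would (1.02 per degree of freedom), and the description of library 1 is that of library 3 with a letter added. Their counts were therefore summed to 1 sample, which leaves 2 samples in this group. Summing had been planned as an alternative and separate libraries as the main analysis, and the roles were exchanged after the counts were seen. With the libraries as deposited, 1218 in place of 1269 and 182 in place of 188 genes passed. The mixed planktonic G. metallireducens libraries shared only 3 to 5 genes with enough counts for this test.

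Each species was fitted on its own in R 4.3.3 with edgeR 4.0.16, with TMM normalization, filterByExpr and 1 mean per group, on 12 samples for S. oneidensis, 8 for G. sulfurreducens and 9 for G. metallireducens. Contrasts were tested by quasi-likelihood F tests, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested (3319, 2172 and 595) with a threshold of 0.05. The common dispersion was 0.113, 0.0394 and 0.0611, and the median prior degrees of freedom were 5.71 for S. oneidensis and 426 for G. metallireducens, while for G. sulfurreducens the fit pooled the spread fully over genes. These p-values measure only the spread between the samples at hand. Levels are counts scaled to the effective library size, and log values were computed with a prior count of 2. For a gene with 1 to 3 counts in a group, the ratio of summed counts is given with its exact 95% counting interval. Species shares were compared by exact permutation of the library labels, for which 0.1 is the smallest p that 3 libraries against 3 can give. Shares in single libraries carry Wilson intervals.

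Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry, for lists with at least 3 tested genes: 32 lists of S. oneidensis, 10 of G. sulfurreducens and 2 of G. metallireducens. The p-values of the lists were adjusted over the lists of a comparison. Membership rests on general knowledge of locus tags and gene clusters. Of the S. oneidensis lists, 16 by symbol pattern were added after the reference table was seen and before any expression value was. A list alone is counted as passing genes when p-values are adjusted over its members only.

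The groups, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names tested members of the metal-reducing, cytochrome, pilin, lactate, hydrogenase and methylcitrate lists, the 3 members with the smallest p of other lists, and the 8 largest rises and 8 largest falls of each comparison (5 and 5 for mixed anode against planktonic cells and mixed against pure planktonic cells). The latter needed an adjusted p under 0.05, a mean of at least 50 counts per library and groups that do not overlap. Genes known by tag alone were limited to 2 that rose and 2 that fell.

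Alternatives were DESeq2's size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a 2-fold minimum change, fits of the 2 compared groups alone, a block for the replicate number, and fits without each library in turn. For species shares the 20 most abundant genes of each species were left out. A fit without the pure S. oneidensis anode library 3 and planktonic library 1 was added after the correlations between libraries were seen. Other splits of the libraries were counted for comparisons of at least 3 samples per group. Shares, tables and figures were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.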

Results

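Gene expression was measured by RNA sequencing in 3 bacteria that can pass electrons to an electrode, Geobacter metallireducens, Geobacter sulfurreducens and Shewanella oneidensis, grown in bio-electrochemical systems either alone or as a mixture of all 3. The 18 libraries fell into 6 groups of 3: biofilms on the anode from each pure culture, cells suspended in the medium (planktonic) from the pure S. oneidensis culture, and biofilm and planktonic cells from the mixed culture. Reads counted in S. oneidensis genes numbered 306719 to 484926 in the pure anode libraries, 423822 to 1575571 in the pure planktonic libraries, 59116 to 151104 in the mixed anode libraries and 219057 to 452935 in the mixed planktonic libraries. G. sulfurreducens genes held 32136 to 372729 counts in the pure anode libraries, 123072 to 432055 on the mixed anode and 6093 to 23466 in mixed planktonic cells. G. metallireducens genes held 42924 to 76590 counts in the pure anode libraries, 12244 to 31449 on the mixed anode and 342 to 944 in mixed planktonic cells, which limits what can be said of this species in suspension.

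The G. sulfurreducens pure libraries 1 and 3 differed by no more than sampling noise allows (chi-square per degree of freedom 1.02 over 1046 genes, p = 0.293), whereas library 2 differed from them by 4.72 and 2.25, and the pair was counted as 1 sample. The pure S. oneidensis and G. sulfurreducens libraries were read at 51 nt and all other libraries at 100 nt, so that read length changed with culture type in the mixed-against-pure comparisons of these 2 species. For G. sulfurreducens the 2 cannot be told apart. For S. oneidensis they can be told apart only where the anode and suspension changed differently. Changes are given as log2 fold changes ± the standard error of the fit, levels as counts scaled to an equal, TMM-corrected total over the genes of the species (CPM) ± SD, and n = 3 libraries per group, except for the 2 pure G. sulfurreducens samples.

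The first comparison asked how the 3 species were distributed between the anode and the medium of the mixed culture. G. sulfurreducens held 66.4% ± 3.57 (SD, n = 3) of the species-assigned counts in the biofilm and 3.68% ± 1.45 in planktonic cells. S. oneidensis showed the opposite distribution, with 27.5% ± 2.91 of the counts on the anode and 96.1% ± 1.34 in suspension. G. metallireducens was the smallest part of both, with 6.14% ± 0.948 on the anode and 0.198% ± 0.110 in suspension. In single libraries, the 95% Wilson interval of the G. metallireducens share was 0.135 to 0.166% in planktonic library 1, 0.111 to 0.131% in library 2 and 0.304 to 0.345% in library 3, which covers counting error only. For each species all 3 anode libraries lay on one side of all 3 planktonic libraries, and the exact two-sided permutation test gave p = 0.1 (0.1 after Benjamini-Hochberg adjustment over 3 species), the smallest value that 3 libraries against 3 allow. A share of counts is not a share of cells. Whether reads of 1 species were counted in genes of another was not tested for these shares, which matters most for the smallest.

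**Figure D1:**
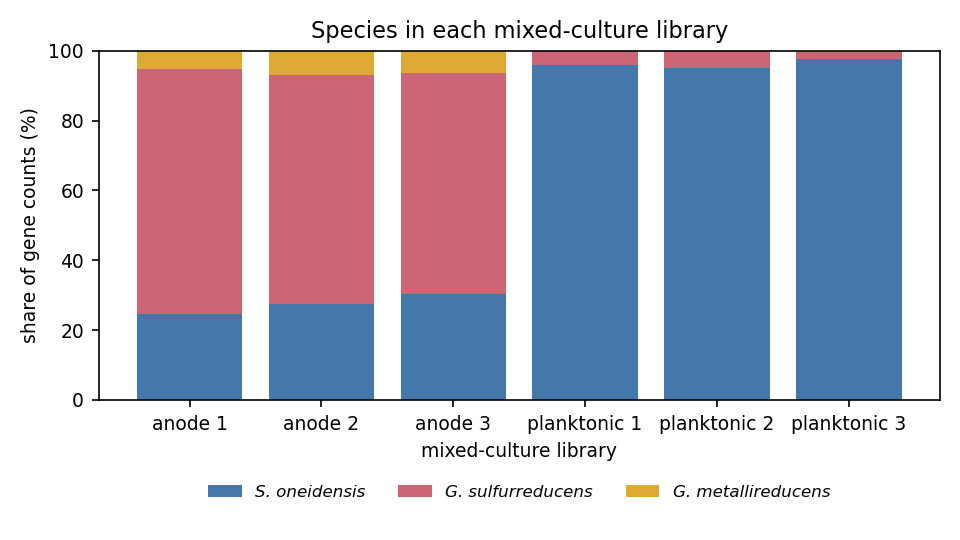
Share of species-assigned gene counts (percent, y axis) of the 3 species (colors) in the mixed culture. Each stacked bar is 1 library, 3 of the anode biofilm and 3 of planktonic cells (x axis). On average S. oneidensis held 27.5% of the counts on the anode and 96.1% in suspension, G. sulfurreducens 66.4% and 3.68%.

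In the pure S. oneidensis culture, biofilm and planktonic cells were compared to find genes that responded to growth on the electrode. The outer-membrane decahaem cytochromes of the metal-reducing pathway varied widely between the libraries of both groups. Mean levels of mtrC were 474 ± 349 CPM on the anode and 575 ± 462 in suspension (log2 change -0.28 ± 0.68). Those of omcA were 904 ± 607 and 963 ± 813 (-0.09 ± 0.68), a spread too wide to show that levels were alike. The inner-membrane quinol oxidase gene cymA gave -0.35 ± 0.45, the hydrogenase gene hyaB 0.27 ± 0.43 and the methylcitrate cycle gene prpC 0.31 ± 0.44. None of these differences passed. With edgeR's quasi-likelihood test, 0 of 3319 genes passed a Benjamini-Hochberg adjusted p of 0.05, 48 had an unadjusted p under 0.05, and DESeq2 also called 0 genes. Of 32 gene lists, 4 passed camera, each with 0 members called: the 54 ribosomal protein genes (median -0.50, adjusted p = 5.86e-08), the overlapping list of 27 genes in and around their main cluster (median -0.53), the 5 tested iron-sulfur cluster assembly genes (median -0.71) and the 15 tested histidine, tryptophan and arginine synthesis genes (median 0.51). With an estimated correlation none of the 4 passed (adjusted p = 0.898, 0.898, 0.0592 and 0.0662, in that order). Fry, which does not compare a list with the other genes, passed 0 of 32 lists.

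In the pure S. oneidensis culture 2 libraries stood apart from their groups. Planktonic library 1 held 9.83% of its gene counts in the 8 oxidative stress defence genes, among them the catalase gene katB with 3.46%, against 0.243% and 0.216% for the list in planktonic libraries 2 and 3. Anode library 3 held 1.98% in the list, against 0.407% and 0.748% in anode libraries 1 and 2. Ribosomal protein genes took 3.67% of planktonic library 1 and 4.43% of anode library 3, against 10.3 to 17.4% of the other pure libraries. Across genes, which are not independent replicates, these 2 libraries had a Spearman correlation of 0.941 with each other. Planktonic library 1 correlated at 0.795 and 0.804 with the other planktonic libraries. Anode libraries 1 and 2 also correlated better with planktonic libraries 2 and 3 (0.930 to 0.942) than with each other (0.927). Without planktonic library 1 the comparison called 87 genes, and without both libraries, an alternative chosen after the data were seen, 31 genes, all of them higher on the anode. Oxidative stress defence then had 5 and 1 of 8 genes called higher on the anode, and histidine, tryptophan and arginine synthesis 3 and 3 of 15.

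**Figure D2:**
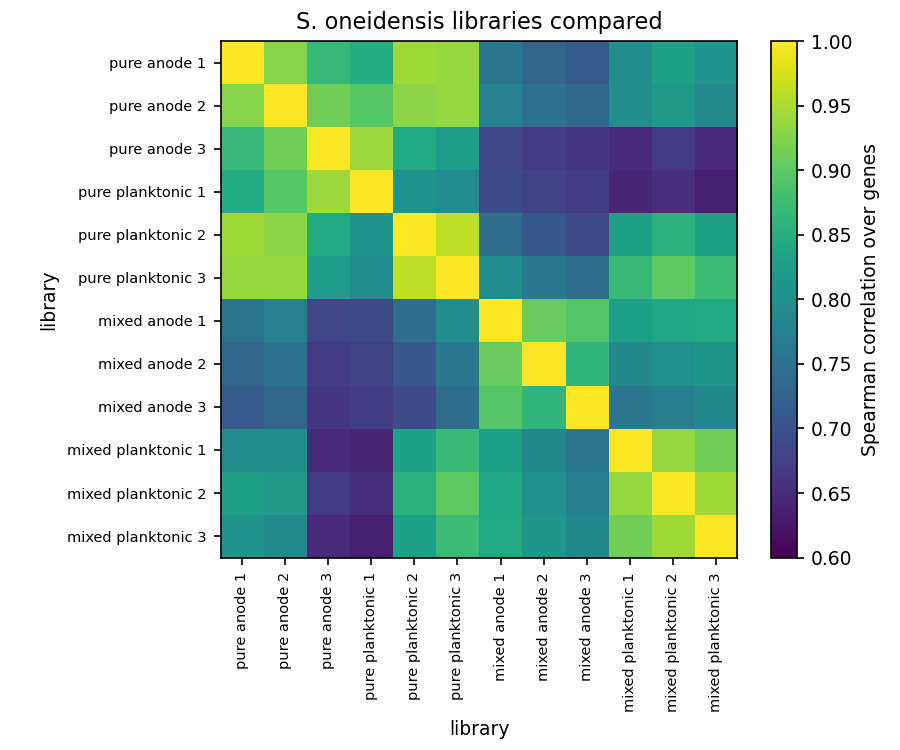
Spearman correlation across genes (color scale) between the S. oneidensis libraries (both axes, named by group and replicate). Pure planktonic library 1 lies closer to pure anode library 3 (0.941) than to pure planktonic libraries 2 and 3 (0.795 and 0.804).

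In the mixed culture the comparison of biofilm with planktonic S. oneidensis asked the same question in the presence of the Geobacter species. The [NiFe] hydrogenase genes hyaA (3.15 ± 0.57), hyaB (2.75 ± 0.43) and cybH (2.49 ± 0.40) rose on the anode, hyaB from 51.3 ± 36.4 to 362 ± 23.0 CPM, while the [FeFe] hydrogenase gene hydA did not pass (0.61 ± 0.44). All 4 genes of the methylcitrate cycle, which oxidizes propionate, fell on the anode, with acnD at -3.02 ± 0.50, prpC at -2.23 ± 0.48, prpF at -2.21 ± 0.58 and prpB at -1.95 ± 0.41. Of the tricarboxylic acid (TCA) cycle genes 7 of 10 fell, with sucC at -2.81 ± 0.60 and sucD at -2.76 ± 0.55. All 8 ATP synthase genes fell (atpA -2.49 ± 0.57), as did 13 of the 27 genes of the ribosomal protein cluster (rplQ -2.79 ± 0.70) and 4 of 7 genes of aerobic terminal oxidases (ccoO -2.11 ± 0.40). Ribosomal protein genes together took 9.07 to 10.8% of S. oneidensis gene counts in the anode libraries and 16.3 to 23.8% in the planktonic libraries. None of the 7 tested genes of the metal-reducing pathway passed, with mtrC at 0.68 ± 0.69, omcA at 0.23 ± 0.68 and cymA at 0.43 ± 0.45. The calls of hyaB, cybH and acnD held without any single library. Calls of other genes named here ended: without mixed anode library 1 prpC (-2.34), prpF (-2.26), atpA (-2.70) and rplQ (-2.99); without library 2 prpF (-2.41), sucC (-2.70), sucD (-2.61), atpA (-2.39), rplQ (-2.77) and ccoO (-1.90); without library 3 prpB (-1.74), prpC (-1.93), prpF (-2.05), sucC (-2.70), atpA (-2.44) and rplQ (-2.66). Without mixed planktonic library 1 the calls of prpF (-1.99), atpA (-2.35) and rplQ (-2.56) ended, and without library 2 those of hyaA (3.05), prpB (-1.80), prpC (-1.98), prpF (-2.10), sucC (-2.74), sucD (-2.68), atpA (-2.49) and rplQ (-2.77). Over the 6 fits without 1 library the members called were 0 to 8 for ATP synthase, 0 to 3 for the ribosomal protein cluster, 0 to 6 for the TCA cycle, 1 to 4 for terminal oxidases and for the methylcitrate cycle, and 2 to 3 for hydrogenases. For the ribosomal protein cluster DESeq2 called 26 and fits of these 6 libraries alone or without the 2 pure libraries that stood apart 27. In the same order these called 9, 9 and 9 genes lower for the TCA cycle, 8, 8 and 8 for ATP synthase and 5, 6 and 6 for terminal oxidases. With a block for the replicate number this cluster held 0 called genes, ATP synthase 4 and the TCA cycle 3, the calls of rplQ (-2.77) and prpF (-2.21) ended, and 34 of 55 named results of this comparison kept their calls.

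By edgeR 338 of 3319 genes passed, 194 higher and 144 lower on the anode, whereas DESeq2 called 212 higher and 283 lower, and edgeR with DESeq2's size factors 165 higher and 175 lower. The gene argC of arginine synthesis (3.91 ± 0.76) and the DNA repair gene recN (3.52 ± 0.59, from 188 ± 5.37 to 2161 ± 113 CPM) rose, and the agglutination gene aggA (-2.34 ± 0.42) fell. Camera passed 18 of 32 lists, and with an estimated correlation none (lowest adjusted p = 0.397), while fry passed 15. The adjusted p given for the lists that follow are those of camera. The hydrogenases (3 of 4 higher, also 3 adjusted over the list alone; adjusted p = 0.000962), the methylcitrate cycle (4 of 4 lower, 4 adjusted over the list alone; 0.000224), the TCA cycle (7 lower, 9 adjusted over the list alone; 1.40e-06), ATP synthase (8 lower, 8 adjusted over the list alone; 8.55e-06), the ribosomal protein cluster (13 lower, 27 adjusted over the list alone; 2.08e-10) and aerobic terminal oxidases (4 lower, 5 adjusted over the list alone; 0.000962) each reached adjusted p = 0.397 with an estimated correlation. The flagellar cluster had 7 of 34 genes higher, 8 adjusted over the list alone, among them the filament cap gene fliD (1.18 ± 0.25; list adjusted p = 0.0229, and adjusted p = 0.397 with an estimated correlation). Lactate oxidation (1 of 5 higher, 2 adjusted over the list alone), other anaerobic reductases (4 of 13 higher, 4 adjusted over the list alone, with the nitrate reductase gene napA at 1.90 ± 0.46) and iron uptake and storage (1 of 6 higher, 3 adjusted over the list alone) also passed camera. Their adjusted p was 0.398, 0.397 and 0.397 with an estimated correlation. The flagellar cluster held 0 to 4 and the anaerobic reductases, lactate oxidation and iron uptake 0 to 1 called genes over the fits without 1 library; DESeq2 called 2 genes of lactate oxidation and 2 of iron uptake, and the fit of these 6 libraries alone 4 and 2. Calls ended without mixed anode library 2 (fliD 1.17 and napA 1.83) or library 3 (fliD 1.15 and napA 1.67). They also ended without mixed planktonic library 1 (fliD 1.05 and napA 1.67), library 2 (argC 4.24, fliD 1.11 and napA 2.14) or library 3 (napA 1.93). These values are those without the library, against 1.18 for fliD, 1.90 for napA and 3.91 for argC with all libraries.

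Of the lists by symbol, ribosomal proteins (12 of 54 lower, adjusted p = 7.00e-12), purine and pyrimidine synthesis (3 of 20 lower, 0.00011), NADH dehydrogenases (1 of 16 lower, 0.000168) and gluconeogenesis and glycolysis (1 of 11 lower, 0.0114) passed camera toward lower values, each with adjusted p = 0.397 with an estimated correlation. Branched-chain amino acid synthesis (2 of 11 higher, median 0.78; adjusted p = 0.397 with an estimated correlation) and oxidative stress defence (0 of 8 called, median 1.42; adjusted p = 0.52 with an estimated correlation) passed toward higher values. The oxidative stress list took 1.34 to 1.68% of S. oneidensis gene counts in the mixed anode libraries and 0.207 to 0.390% in the mixed planktonic libraries, a shift in the same direction as in the 2 pure libraries that stood apart. In the fit of these 6 libraries alone and in the fit without those 2 pure libraries 5 of the 8 genes were called higher, katB at 4.22 and 4.16, ahpF at 3.20 and 3.14, and ahpC at 2.73 and 2.67, so the 0 calls do not show that these genes stayed level. Fatty acid synthesis (1 higher, 1 lower of 9; adjusted p = 0.398 with an estimated correlation) and aminoacyl-tRNA synthetases (1 higher, 1 lower of 25; adjusted p = 0.52 with an estimated correlation) passed toward lower values. The higher member of the latter, hisG, is an enzyme of histidine synthesis that the symbol pattern took in, as it did cysQ, glnG, gltS and proQ. When 1 library was left out ribosomal proteins held 0 to 4 called genes, NADH dehydrogenases 0 to 2, purine and pyrimidine synthesis, gluconeogenesis and branched-chain amino acid synthesis 0 to 1 each, and the fatty acid and aminoacyl-tRNA lists 0 genes called higher. For ribosomal proteins, purine and pyrimidine synthesis, NADH dehydrogenases, gluconeogenesis and branched-chain amino acid synthesis DESeq2 called 35, 6, 5, 5 and 2 genes, the fit of these 6 libraries alone 46, 12, 11, 6 and 3, the fit without the 2 pure libraries that stood apart 46, 12, 10, 6 and 3, and a block for the replicate number 0, 0, 0, 1 and 1. The number of calls fell without any one of these 6 libraries: it was 129, 80 and 80 without mixed anode library 1, 2 or 3, and 90, 46 and 198 without mixed planktonic library 1, 2 or 3. A fit of these 6 libraries alone called 857 genes, and a fit without the 2 pure libraries that stood apart called 832. Those 2 libraries are not part of this contrast and enter it only through the spread, filter and normalization that the fit shares. The count of 338 thus also depended on the pure libraries.

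The comparison of mixed with pure anode biofilms asked what the company of the Geobacter species changed in S. oneidensis on the electrode. All 4 hydrogenase genes rose, hyaA by 4.32 ± 0.59 (from 12.4 ± 9.87 to 254 ± 121 CPM), hyaB by 3.33 ± 0.43, cybH by 2.87 ± 0.39 and hydA by 2.00 ± 0.47. In pure anode libraries 1, 2 and 3 hyaA had only 6, 10 and 1 counts and hydA 9, 6 and 2, so both rises rest on few reads. All 5 genes of lactate oxidation and uptake rose, SO_1520 by 3.53 ± 0.79 (from 176 ± 139 to 2055 ± 403 CPM) and SO_1522 by 2.57 ± 0.50, as did 6 of 7 formate dehydrogenase genes, SO_4513 by 3.63 ± 0.49. The formate dehydrogenases rose in 6 of 7 cases in planktonic cells too, so for them read length and culture cannot be told apart. Lactate oxidation and the metal-reducing pathway also passed camera toward higher values in planktonic cells. A part of read length is therefore not excluded for these 2 lists. The methylcitrate cycle fell in all 4 genes, acnD from 2148 ± 1010.0 to 143 ± 25.0 CPM (-3.89 ± 0.51), prpC by a log2 change of -3.27 ± 0.50, prpF of -3.18 ± 0.58 and prpB of -2.43 ± 0.41. Of the metal-reducing pathway 2 of 7 genes rose, cymA (2.12 ± 0.47) and the periplasmic fumarate reductase gene fccA (2.10 ± 0.55). The values of mtrC (1.95 ± 0.71, adjusted p = 0.0693), omcA (1.77 ± 0.70, 0.0929) and mtrA (1.69 ± 0.65, 0.0859) did not pass over all genes, and all 7 genes passed when adjusted over the list alone. The number of called genes in this list rested on the method: 5 by DESeq2, 6 in a fit of the 2 groups alone, 6 without the 2 pure libraries that stood apart, and 1 to 2 over the fits without 1 library. The fit of the 2 groups and the one without the 2 pure libraries each called mtrC, omcA and mtrA. The call of fccA ended without pure anode library 3 (1.69) and without mixed anode library 1, 2 or 3 (2.11, 2.10 and 2.07), and that of hydA without mixed anode library 1 (1.98). Over the fits without 1 library the formate dehydrogenases held 3 to 6 called genes, lactate oxidation 2 to 4, the hydrogenases 3 to 4 and the methylcitrate cycle 4 in each.

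Of 3319 genes 631 passed (edgeR), 315 higher and 316 lower in the mixed biofilm. TCA cycle genes fell in 6 of 10 cases, with sucD at -2.53 ± 0.54, sucC at -2.36 ± 0.59 and odhB at -2.17 ± 0.49. Other anaerobic reductases rose in 7 of 13 cases, napA by 2.04 ± 0.44, and genes of the biofilm matrix and adhesion fell in 3 of 6 cases, among them the agglutination gene aggA (-2.04 ± 0.42) and mxdA (-1.46 ± 0.34). Histidine, tryptophan and arginine synthesis fell in 2 of 15 cases (argH -3.83 ± 0.63). Of other genes with a symbol, suhB, of inositol phosphate metabolism, rose by 2.63 ± 0.43, and hppD of tyrosine breakdown (-4.96 ± 0.55) and the aldehyde dehydrogenase gene exaC (-4.70 ± 0.65) fell. Camera passed 9 of 32 lists: hydrogenases (adjusted p = 0.000376; 4 adjusted over the list alone), formate dehydrogenases (0.000376; 6), methylcitrate cycle (0.000376; 4), TCA cycle (0.00107; 8), lactate oxidation (0.00107; 5), other anaerobic reductases (0.00107; 7), the metal-reducing pathway (0.00107; 7), histidine, tryptophan and arginine synthesis (0.0141) and biofilm matrix and adhesion (0.0213; 4). None of them passed camera with an estimated correlation, where the adjusted p was 0.23, 0.386, 0.386, 0.57, 0.399, 0.386, 0.57, 0.386 and 0.399 in that order. By fry 11 of 32 lists passed. ATP synthase (1 of 8 lower, 3 adjusted over the list alone), aerobic terminal oxidases (2 of 7 lower, 4 adjusted over the list alone), acetate and formate fermentation (2 of 4 higher, 3 adjusted over the list alone, pflB 2.01 ± 0.55) and heat shock chaperones (0 of 7) did not pass camera. The count of calls fell to 406 without pure anode library 3 and to 303, 372 and 415 without mixed anode library 1, 2 or 3. The call of sucC ended without mixed anode library 2 or 3 (-2.24 and -2.23), that of mxdA without mixed anode library 1 (-1.33) and that of pflB without pure anode library 1 or 3 (2.03 and 1.70) or mixed anode library 1, 2 or 3 (2.04, 1.91 and 2.06). Over the fits without 1 library the TCA cycle held 2 to 7 called genes, the anaerobic reductases 3 to 5, the biofilm genes 1 to 3, the histidine, tryptophan and arginine list 1 to 2, ATP synthase 0 to 2, acetate and formate fermentation 0 to 2 and the terminal oxidases 0 to 4. ATP synthase had 3 called genes by DESeq2, 3 in a fit of the 2 groups alone and 8 without the 2 pure libraries that stood apart, the terminal oxidases 4 in each of these, and the histidine, tryptophan and arginine list 1, 4 and 4. With a block for the replicate number the TCA cycle held 4 called genes, lactate oxidation 3, the histidine, tryptophan and arginine list 1 and ATP synthase 0. Oxidative stress defence and the ribosomal protein cluster had 0 calls with all libraries, but 2 genes higher and 1 lower in the fit of the 2 groups and 4 higher and 18 lower without the 2 pure libraries that stood apart.

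**Figure D3:**
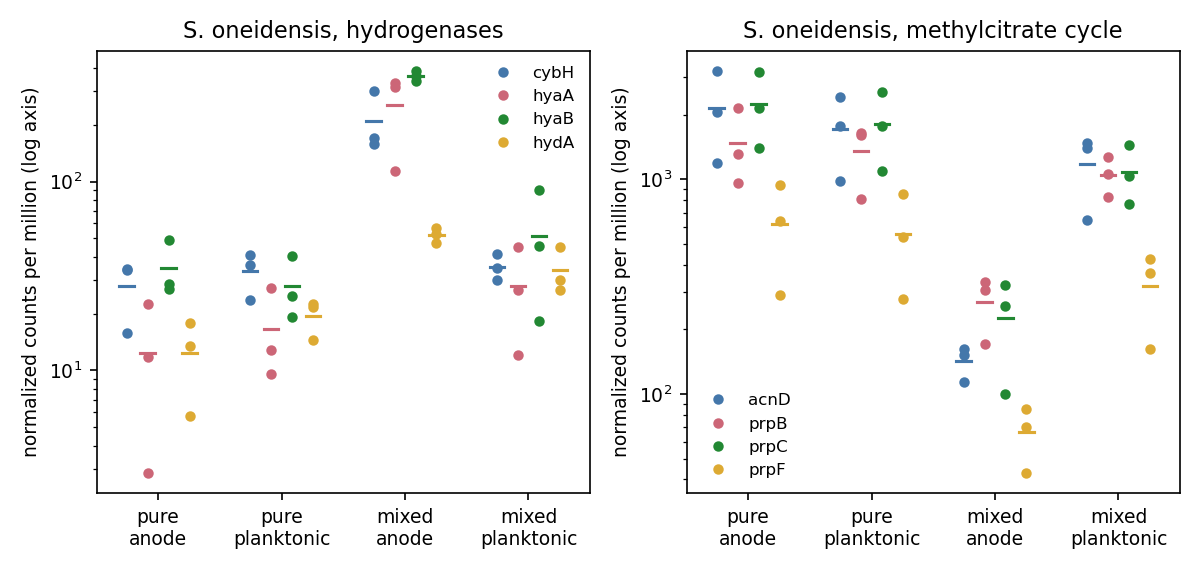
Levels (CPM of S. oneidensis gene counts, log axis) of the hydrogenase genes cybH, hyaA, hyaB and hydA (left) and the methylcitrate cycle genes acnD, prpB, prpC and prpF (right) in the 4 groups of libraries; points are libraries and bars are group means. The mean of hyaB was 362 ± 23.0 CPM (SD) on the mixed anode and 35.0 ± 12.4 on the pure anode.

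Planktonic S. oneidensis cells of the mixed and the pure culture were compared in the same way. Formate dehydrogenase genes rose in 6 of 7 cases, SO_4513 by 3.38 ± 0.48 and SO_4515 by 2.88 ± 0.33. Branched-chain amino acid synthesis fell in 6 of 11 cases, with ilvC at -1.95 ± 0.39 and leuA at -1.32 ± 0.33, and histidine, tryptophan and arginine synthesis in 4 of 15, with argC at -2.96 ± 0.74 and hisG at -2.66 ± 0.56. The cysteine synthase gene cysK (-2.30 ± 0.56), the iron-sulfur regulator gene iscR (-2.09 ± 0.49), the pilin-like gene pilV (-1.60 ± 0.31) and mxdA (-1.84 ± 0.30) fell. Of other genes with a symbol, the ornithine decarboxylase gene speF rose (2.67 ± 0.58), and exaC (-7.33 ± 0.79, from 848 ± 468 to 5.06 ± 1.18 CPM) and azu (-5.12 ± 0.92) fell. The formate dehydrogenases, exaC and mxdA changed in the same direction on the anode, so for them read length and culture cannot be told apart. Lists with genes called mostly lower in both comparisons included histidine, tryptophan and arginine synthesis and branched-chain amino acid synthesis. Iron-sulfur cluster assembly and sulfate assimilation and cysteine synthesis were 2 more. Read length is not excluded for these lists either. The 4 hydrogenase genes did not pass, with values of 0.12 to 0.85, nor did the 4 methylcitrate genes (-0.81 to -0.36). Without pure planktonic library 1, the library with the high oxidative stress share (9.83%), argC stood at -1.61 and was not called, while iscR (-1.21) and cysK (-1.37) kept their calls at smaller values. Calls also ended without mixed planktonic library 1 (argC (-2.97), leuA (-1.07) and cysK (-2.13)), library 2 (argC (-3.30), hisG (-2.27), leuA (-1.13), cysK (-2.42) and iscR (-2.07)) and library 3 (argC (-2.66), hisG (-2.54), cysK (-2.35) and iscR (-1.93)). Over the fits without 1 library the formate dehydrogenases held 3 to 6 called genes, branched-chain amino acid synthesis 1 to 5 and the histidine, tryptophan and arginine list 0 to 6. In a fit of these 6 libraries alone the last 2 lists held 2 and 1 called genes, and the calls of argC (-2.97), iscR (-2.10) and leuA (-1.32) ended. With a block for the replicate number the 3 lists held 4, 4 and 1 called genes, and the call of argC ended as well.

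In this comparison 461 of 3319 genes passed (edgeR), 144 higher and 317 lower in the mixed culture. Camera passed 13 of 32 lists and none with an estimated correlation (lowest adjusted p = 0.232), while fry passed 3. The adjusted p given for the lists that follow are those of camera. Formate dehydrogenases (adjusted p = 2.69e-05; 6 adjusted over the list alone), branched-chain amino acid synthesis (0.00222) and histidine, tryptophan and arginine synthesis (0.00222) each had adjusted p = 0.232 with an estimated correlation. Toward higher values, ribosomal proteins (5 of 54 called), the ribosomal protein cluster (0 of 27, 0 adjusted over the list alone), purine and pyrimidine synthesis (3 of 20, pyrE 1.59 ± 0.28), gluconeogenesis and glycolysis (2 of 11) and the metal-reducing pathway (0 of 7, 2 adjusted over the list alone, cymA 1.34 ± 0.45) passed as well. So did acetate and formate fermentation (0 of 4, 3 adjusted over the list alone), aminoacyl-tRNA synthetases (1 higher, the transporter gene gltS, and 1 lower, hisG, of 25), NADH dehydrogenases (2 of 16), lactate oxidation (0 of 5, 0 adjusted over the list alone) and ATP synthase (0 of 8, 0 adjusted over the list alone). With 1 library left out the called genes numbered 0 to 10 for ribosomal proteins, 1 to 10 for purine and pyrimidine synthesis, 0 to 4 for gluconeogenesis and 0 to 1 for NADH dehydrogenases; in a fit of these 6 libraries alone they were 1, 1, 0 and 0, by DESeq2 13, 5, 3 and 2, with a block for the replicate number 1, 1, 0 and 0, and without the 2 pure libraries that stood apart 13, 6, 2 and 2. Without pure planktonic library 3 the metal-reducing pathway held 5 called genes, acetate and formate fermentation 4 and lactate oxidation 4, by DESeq2 3, 3 and 0, and without the 2 pure libraries 3, 2 and 1. For ATP synthase the adjusted p was 0.623, and for the other lists of both sentences 0.588, with an estimated correlation. The catalase gene katB (-6.35 ± 1.92) and the peroxidase reductase gene ahpF (-4.53 ± 1.37) were called lower, but without pure planktonic library 1, which held 9.83% of its counts in such genes, their values turned to 0.56 and 0.11 and neither passed. Neither call held without mixed planktonic library 1, 2 or 3 either, at -6.18, -5.96 and -7.13 for katB and -4.42, -4.22 and -5.02 for ahpF. The count of calls was 162, 148 and 158 without mixed planktonic library 1, 2 or 3, and 182 in a fit of these 6 libraries alone.

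Whether the anode-against-planktonic change of S. oneidensis differed between mixed and pure culture was tested as an interaction. The hydrogenase genes had the positive differences cybH 2.75 ± 0.55, hyaA 3.62 ± 0.84, hyaB 2.48 ± 0.60 and hydA 1.25 ± 0.60, and the methylcitrate genes the negative differences acnD -3.34 ± 0.65, prpC -2.54 ± 0.65, prpF -2.37 ± 0.75 and prpB -2.07 ± 0.56. None passed over all genes, the lowest adjusted p being 0.0807 for cybH, whereas without the 2 pure libraries that stood apart 3 of the 4 hydrogenase genes (median 2.63) and 3 of the 4 methylcitrate genes (median -2.05) passed. Without pure planktonic library 1 alone 3 and 1 passed, and by DESeq2 1 and 3. Other lists also gained negative differences in the fit without the 2 pure libraries that stood apart. There 16 genes of the ribosomal protein cluster, 6 of ATP synthase, 5 of the TCA cycle and 4 of the terminal oxidases passed, against 0 with all libraries. Adjusted over the list alone, 3 of 4 hydrogenase genes, 4 of 4 methylcitrate genes, 6 of 10 TCA cycle genes and 4 of 7 terminal oxidase genes passed. edgeR called 0 of 3319 genes (471 at an unadjusted p under 0.05) and DESeq2 61. Camera passed 12 of 32 lists, with hydrogenases at adjusted p = 3.95e-05 and the methylcitrate cycle at 2.54e-05, and none with an estimated correlation (adjusted p = 0.196 and 0.457). The number of called genes was 27 without pure planktonic library 1, 4 without pure planktonic library 3, 3 and 2 without mixed anode library 2 or 3, and 156 without the 2 pure libraries that stood apart.

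G. sulfurreducens was compared between the mixed and the pure anode biofilm. Its genes carried no names in the sources used here, and lists were drawn up by locus tag. The 4 genes of the Hyb uptake hydrogenase rose, by log2 changes of 1.05 to 4.68 (4 adjusted over the list alone; camera adjusted p = 0.000945, and adjusted p = 0.417 with an estimated correlation). Outer-surface cytochromes, which carry electrons to acceptors outside the cell, rose in 6 and fell in 2 of 10 cases (6 and 2 adjusted over the list alone; -1.75 to 1.75). Periplasmic and inner-membrane cytochromes rose in 3 and fell in 1 of 6 cases (3 and 1 adjusted over the list alone; largest rise 3.30), type IV pilus genes rose in 5 of 10 (5 adjusted over the list alone) and heat shock chaperones in 3 of 3 (3 adjusted over the list alone). Beyond the lists, GSU0787 (6.47 ± 0.50, from 19.5 ± 2.29 to 1884 ± 956 CPM) and GSU0786 (6.11 ± 0.48) rose most. Their tags directly follow those of the Hyb list (GSU0782 to GSU0785), so their rise may not be separate from that of Hyb. GSU0938 fell from 821 ± 183 to 10.3 ± 8.22 CPM (-6.66 ± 0.46). GSU1340 had 294 counts in the pure samples and 1 in the mixed ones, a ratio of 0.00237 mixed to pure with a 95% counting interval of 5.98e-05 to 0.0133.

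By edgeR 1269 of 2172 genes passed, 591 higher and 678 lower in the mixed biofilm. The acetate oxidation and TCA cycle list had 4 higher and 2 lower of 12 genes, the NADH dehydrogenase cluster 2 higher and 1 lower of 14 (0 adjusted over the list alone), ATP synthase 2 higher and 1 lower of 7, formate dehydrogenase 1 lower of 3 and the extracellular polysaccharide cluster 0 of 5. Adjusted over the list alone the counts were the same except where given. Camera passed the Hyb list and none of the 9 others, whose adjusted p ran from 0.0934 to 0.646. By fry 3 of 10 lists passed. Both tested nitrogen fixation genes fell. GSU2821 (-6.74 ± 0.66) had 32 and 61 counts in the pure samples and 0, 0 and 1 in the mixed libraries. GSU2820 (-7.63 ± 0.84) had 23 and 42 counts in the pure samples and 0 in each mixed library. The single tested gene of the flagellar clusters did not pass (0.46 ± 0.93), and neither list was large enough for a list test. The spread of this species was pooled over genes, so its p-values rest on a common estimate from 8 samples. Over the fits without 1 library, outer-surface cytochromes held 3 to 5 genes called higher, type IV pili 4 to 7, Hyb 3 to 4, acetate oxidation 0 to 6 and the NADH dehydrogenase cluster 0 to 4. Of the latter DESeq2 called 1 gene and a fit of the 2 groups alone 4. ATP synthase held 1 to 2 genes called higher, heat shock chaperones 2 to 3 and formate dehydrogenase 0 to 1 called lower when 1 library was left out.

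In the mixed culture G. sulfurreducens on the anode was compared with the few G. sulfurreducens counts from planktonic cells. Genes of the NADH dehydrogenase cluster, part of the respiratory chain, rose on the anode in 11 of 14 cases (13 adjusted over the list alone; 0.85 to 2.67), Hyb in 4 of 4 (4 adjusted over the list alone; 1.10 to 1.30) and acetate oxidation and the TCA cycle in 5 of 12, with 1 lower (7 and 1 adjusted over the list alone). Type IV pilus genes fell in 2 of 10 cases (3 adjusted over the list alone; median -1.06), the extracellular polysaccharide cluster in 1 of 5 (3 adjusted over the list alone; median -1.54) and outer-surface cytochromes in 1 of 10 (1 adjusted over the list alone). GSU1305 had 1046 counts on the anode and 1 in suspension, a ratio of 53.4 with a 95% counting interval of 9.57 to 2112, and GSU3242 had 853 and 1 (43.6, 7.80 to 1723). Among genes with a mean of at least 50 counts per library, GSU1640 (-2.67 ± 0.35) and GSU0012 (-2.10 ± 0.34) fell most.

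By edgeR 188 of 2172 genes passed, 122 higher and 66 lower, against 88 and 78 by DESeq2 and 68 and 91 in a fit of these 6 libraries alone. The median change of all genes was 0.28, and 0.18 with DESeq2's size factors. Camera passed 4 of 10 lists, type IV pili (adjusted p = 0.00156), the polysaccharide cluster (0.00167), the NADH dehydrogenase cluster (0.00171) and outer-surface cytochromes (0.0112). With an estimated correlation the adjusted p was 0.418, 0.418, 0.441 and 0.418. By fry 4 of 10 lists passed. Hyb did not pass camera (adjusted p = 0.0561), nor did acetate oxidation (0.103), ATP synthase with 1 of 7 higher (1 adjusted over the list alone), formate dehydrogenase with 0 of 3, heat shock chaperones with 1 of 3 higher (2 adjusted over the list alone) or periplasmic and inner-membrane cytochromes with 1 of 6 higher (4 higher and 1 lower adjusted over the list alone). Of the lists too small for a test, the single flagellar gene fell and the 2 nitrogen fixation genes did not pass. The count of calls fell to 109 without mixed anode library 1 and to 66 without mixed planktonic library 2. Over the fits without 1 library the NADH dehydrogenase cluster held 4 to 12 called genes, Hyb 0 to 4, acetate oxidation 3 to 6 higher and type IV pili 0 to 2. The polysaccharide cluster, outer-surface cytochromes, ATP synthase and heat shock chaperones held 0 to 1 each and periplasmic and inner-membrane cytochromes 1 to 2. Without a filter on low counts 0 outer-surface cytochromes were called. A fit of these 6 libraries alone called 6 genes of the NADH dehydrogenase cluster, 1 of Hyb and 3 of acetate oxidation, and DESeq2 7, 4 and 4.

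G. metallireducens, whose genes were likewise known by tag alone, was compared between the mixed and the pure anode biofilm, all read at 100 nt. The benzoate degradation cluster, through which this species breaks down aromatic compounds, fell in 10 of 31 tested genes (16 adjusted over the list alone; median -0.87, -1.63 to 0.91) and passed camera (adjusted p = 7.95e-10), also with adjusted p = 0.00262 with an estimated correlation. The 7 tested flagellar genes showed 0 calls (0 adjusted over the list alone; median 0.00 after rounding). Among genes with a mean of at least 50 counts per library, Gmet_2742 (1.58 ± 0.33) and Gmet_1125 (1.55 ± 0.33) rose most, and Gmet_3186 (-2.37 ± 0.37) and Gmet_1930 (-2.32 ± 0.38, from 6134 ± 2897 to 1190.0 ± 305 CPM) fell most. By edgeR 38 of 595 genes passed, 12 higher and 26 lower in the mixed biofilm. The mixed anode libraries held 9.37 to 13.7 G. sulfurreducens counts per G. metallireducens count. Whether reads of G. sulfurreducens were counted in G. metallireducens genes was not tested, for the benzoate cluster or any other gene. The single tested gene of the pilin and cytochrome pair linked to direct electron transfer between species did not pass (adjusted p = 0.0521). Without mixed anode library 1 the comparison called 19 genes, and the benzoate cluster held 4 to 10 called genes over the fits without 1 library.

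Between the mixed anode and mixed planktonic libraries, G. metallireducens rested on 342, 574 and 944 counts in suspension. Whether some of these were reads of the other species was not tested. Gmet_3254 had 532 counts on the anode and 3 in suspension, a ratio per gene total of 5.03 with a 95% counting interval of 1.71 to 24.5, and Gmet_0342 had 337 and 2 (4.78, 1.31 to 39.7). Gmet_1930 and Gmet_1929, which the naming rule did not cover and which were chosen after their values were seen, fell on the anode (-3.80 ± 0.46 and -3.94 ± 0.64), Gmet_1930 having 22, 17 and 6 counts in the anode libraries and 4, 15 and 22 in the planktonic libraries. By edgeR 54 of 595 genes passed, 48 higher and 6 lower on the anode, against 28 and 8 by DESeq2. The median change of all genes was 1.24, and 1.08 with DESeq2's size factors in edgeR, which called 34 genes, so that a rise below these values was no rise relative to the other genes. In simulated counts of this comparison, which held as many falls as rises, only rises were recovered, so the excess of genes higher on the anode cannot be read as a direction of response. The benzoate cluster had 0 of 31 genes called (0 adjusted over the list alone) and a median of 0.77, while camera, which compares it with the other genes, pointed to lower values (adjusted p = 0.475). The flagellar list had 0 of 7 called (0 adjusted over the list alone; adjusted p = 0.536), and the single tested gene of the pilin and cytochrome pair did not pass (adjusted p = 0.0828). Fry passed 2 of 2 lists, but it does not set them against the median change of 1.24 of all genes. The count of calls was 28 and 23 without mixed planktonic library 1 or 2, and 23 in a fit of these 6 libraries alone.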

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

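The counts of library splits were planned, whereas all tests of explanations given here (exchanged labels, a wrong label, an even background, read length, Geobacter reads and low counts) were chosen after the results were seen.

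The hydrogenase genes of S. oneidensis stood out because their anode-against-planktonic change differed between mixed and pure culture, with a median difference of 2.61 (log2) over 4 genes and an adjusted p of 0.0085 by fry over 32 lists. No other list had an adjusted p under 0.05 by fry, and the rule that chose this value by fry was set after the list results were seen. With camera and an estimated correlation the adjusted p was 0.196. The list held few reads in the pure anode libraries, hyaA 1 to 10 counts and hydA 2 to 9. For the number of called genes in this interaction, 0, all 100 of 100 splits drawn called as many, and the highest called 922. Since 0 was called, every split must reach as many, so this count neither excludes chance nor speaks for it. The split that called 922 kept the mixed libraries in their groups and set pure anode libraries 1 and 3 with planktonic library 1 against the other pure ones, which points to structure among the pure samples.

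For the rise of the hydrogenase genes and the fall of the methylcitrate genes in the mixed anode biofilm, read length was weighed first, since the pure libraries were read at 51 nt and the mixed ones at 100 nt. An effect of read length alone would move a gene alike on the anode and in suspension. The median interaction was 2.61 for the hydrogenases, which argues against it as the whole cause for these genes. The hydrogenases had been singled out by this same value, so it is no independent test of the pattern itself. For the methylcitrate genes the median interaction was -2.45 (fry p of 0.00564 before and 0.0902 after adjustment in an edgeR and limma fit of 12 libraries). The rule written for this test used the unadjusted p and was met, which would argue against read length as the whole cause. Since the adjusted p did not pass, read length was nevertheless kept open for the methylcitrate genes. Without the 2 pure libraries that stood apart the medians were 2.63 and -2.05. Reads of the Geobacter species counted in S. oneidensis genes stayed open for the hydrogenases: the ribosomal protein genes, taken as those most likely to share reads although shared sequence was not measured, were lower on the mixed anode by a median of -1.41, but their median level of 3497 CPM against 29.0 CPM for the hydrogenases could hide added reads. The reading of this test was tightened after its first result. A response of S. oneidensis to the Geobacter species or to their products also stayed open and was not tested.

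The pure S. oneidensis anode library 3 and planktonic library 1 lay closer to each other (Spearman correlation across genes 0.941) than to their own groups. An exchange of their labels would need anode library 3 to resemble the planktonic libraries 2 and 3, but its highest correlation with them lay below its lowest with the anode libraries 1 and 2 (0.844 against 0.866, difference -0.0225). A wrong label of planktonic library 1 alone had the values it needs: its lowest correlation with an anode library exceeded its highest with the planktonic libraries by 0.0436 (0.848 against 0.804). However, anode libraries 1 and 2 also correlated better with planktonic libraries 2 and 3 (0.930 to 0.942) than with each other (0.927). The correlations thus do not separate the labels and decide neither question. An even background of reads such as genomic DNA would pull the ratio of reads in no gene to reads in genes toward 1.32 or less, whereas the lower ratio of the 2 libraries was 3.44 and the other 4 pure libraries had 1.83 to 2.64. This test replaced an earlier one, the SD of log2 counts per base, which was 1.81 and 1.76 in the 2 libraries against 1.71 to 1.80 in the other 4. The planktonic library 1 may be mislabelled, or its culture may have been in another state, with 9.83% of counts in oxidative stress genes. These values do not decide between the 2, and no biological explanation was tested.

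Of the G. metallireducens genes called between mixed anode and planktonic libraries, 48 of 54 were higher on the anode, with a median change of 1.24 over all genes. Mixed anode libraries thinned to the planktonic totals gave a median change of 1.11 against the full libraries (0.943 to 1.27 over 20 thinnings), so low counts may account for the shift of the median. They called 0 to 5 genes, so the thinning matched the shift and not the number of calls. The bound of 0.62 that the test used was set after a simulation and the observed shift had been seen. The same thinning gave G. sulfurreducens a median of 0.331 (0.159 to 0.385) against the observed 0.28.

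The remaining counts of splits stand beside their results. For pure S. oneidensis, anode against planktonic, where 0 genes were called, 10 of 10 splits called as many, as they must where 0 is the real count, and the highest called 468: it set anode library 1 and planktonic libraries 2 and 3 against the others, which points to a structure of the samples other than their group. In mixed S. oneidensis, anode against planktonic, 1 of 10 splits called as many (338; highest other 0). For mixed against pure S. oneidensis it was 1 of 10 on the anode (631; highest other 0) and 1 of 10 in suspension (461; highest other 0). G. sulfurreducens in the mixed culture gave 1 of 10 (188; highest other 0), G. metallireducens 1 of 10 for mixed against pure (38; highest other 0) and 1 of 10 for anode against planktonic (54; highest other 1). In each of these, 10 splits are too few for a share under 0.05. The mixed-against-pure comparison of G. sulfurreducens, with 2 pure samples, had no such count.

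In data outside the main measurement, the tally for low alignment quality held a median of 90.0% of the reads of a library, and the reads in no gene were a median of 2.05 times those in genes. What these reads were was not analysed here. Groups of 3 libraries were not tested for single outlying samples.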

How the results depend on the processing

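All alternatives reported here were planned, except the fit without pure anode library 3 and pure planktonic library 1, chosen after the data were seen. The as-deposited G. sulfurreducens fit had been planned as the first analysis and changed places with the summed fit after the data were seen. No named gene changed direction under DESeq2's size factors, the DESeq2 test, no filter, or the 2-group fits, and of 2769 values for 234 gene results 2246 stayed on the same side of the threshold, 486 lost and 33 gained a call and 4 reversed. Of 974 counts of called list members 579 stayed within 1.5 times, and of 184 list tests 123 kept their side with an estimated correlation. The cause of a moved count was not tested unless fewer samples or genes show it. Depth limits G. metallireducens in suspension most (342 to 944 counts) and next G. sulfurreducens in suspension (6093 to 23466).

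The reversed values were those of katB (-6.35) and of ahpF in S. oneidensis, mixed against pure culture, planktonic cells (-4.53). Without pure planktonic library 1 ahpF was 0.11 and katB 0.56, and without both doubtful libraries they were 0.11 and 0.56, because the high level lay in that library. Leaving out other single libraries, ahpF reached -5.09 and katB -7.13.

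Leaving out 1 library at a time, the number of genes called ran, for S. oneidensis, from 0 to 87 in pure culture (0 with all), 46 to 198 between mixed anode and planktonic cells (338), 303 to 468 between mixed and pure anodes (631), 148 to 666 between mixed and pure planktonic cells (461) and 0 to 27 for the interaction (0). It ran from 66 to 194 for G. sulfurreducens in the mixed culture (188), and for G. metallireducens from 19 to 39 on the anode (38) and 23 to 71 in the mixed culture (54). For G. sulfurreducens on the anode it stayed at 1048 to 1193 (1269). Where this leaves a single sample in a group, that sample is assumed to vary like the other groups. Fitting only the 2 compared groups called 857 genes in mixed S. oneidensis, 182 between planktonic S. oneidensis cultures and 23 in mixed G. metallireducens. These fits held fewer libraries and genes, and their spread was estimated from the compared groups alone. Without the 2 doubtful libraries 31 genes passed in pure culture, 832 in mixed culture and 156 for the interaction, for which DESeq2 called 61. DESeq2's size factors lowered the count of G. metallireducens in the mixed culture to 34.

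With the replicate number as a block, 172 genes passed between mixed S. oneidensis anode and planktonic cells and 231 between planktonic cultures, the other counts staying within 1.5 times. Pairing was checked by correlating, across genes, the deviations of log levels from the group mean. In none of 8 pairs of groups did these deviations correlate above 0.1 for every pair of libraries with the same number. Best matches with the own number were 0 to 2 of 3. The check thus showed no pairing, but with 3 libraries per group it cannot exclude one.

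Leaving out the 20 most abundant genes of each species moved the anode-minus-planktonic difference of species shares from -68.6 to -65.3 points for S. oneidensis, from 62.7 to 59.2 for G. sulfurreducens and from 5.94 to 6.13 for G. metallireducens. Leaving out the anode and the planktonic library of 1 replicate number, the difference ran from -69.4 to -67.3, 60.9 to 63.7 and 5.47 to 6.42.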

Other observations

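The lists given here were fixed before any expression value was seen, and no test was added to them.

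Neither prophage list of S. oneidensis passed camera. On the mixed against the pure anode, 0 of 14 tested genes of the lambdaSo prophage were called (median -0.02, adjusted p = 0.633 by camera) and 0 of 8 of the MuSo2 prophage (median -1.08, adjusted p = 0.223). Between mixed anode and planktonic cells, 1 of 14 lambdaSo genes was higher (0 to 1 when 1 library was left out; adjusted p = 0.647) and 0 of 8 MuSo2 genes were called (adjusted p = 0.383). On the mixed against the pure anode 1 MuSo2 gene was called lower by DESeq2 and in the fit of the 2 groups, which also called 1 lambdaSo gene higher and 1 lower. Heat shock chaperones showed 0 of 7 calls in both comparisons, with medians of -0.05 and -0.54, but 2 higher and 2 lower between mixed anode and planktonic cells when these 6 libraries were fitted alone. The flagellar cluster had 4 of 34 genes higher on the mixed than on the pure anode (adjusted p = 0.106), among them fliD (1.18 ± 0.25), and 1 of 34 higher in planktonic cells of the mixed against the pure culture (0 to 1 when 1 library was left out and 0 in the fit of the 2 groups; adjusted p = 0.823). Cytochrome c maturation had 1 of 7 genes higher in each of the 2 anode comparisons (adjusted p = 0.393 for mixed against pure, where it was 0 to 1 when 1 library was left out, and 0.0504 for anode against planktonic cells, where the fit of the 2 groups called 3).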
